A study of Mus musculus with 12 samples.

How the data were processed

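RNA was measured in ET cells, which the labels describe as a mouse line of fetal cortical thymic epithelium, after 2, 4 or 6 h with 5 nM TCDD, a dioxin that binds the aryl hydrocarbon receptor (AhR), or with its solvent, 1,4-dioxane at 0.05% by volume. The 12 Affymetrix arrays made 6 groups of 2, 1 group per treatment and time. RNA was isolated with TRIzol and labelled by the manufacturer's standard protocol, per the labels' protocols. The design text calls the arrays of a group biological duplicates but does not say which step was repeated, so p-values measured only the spread between these arrays, part of which could be technical. The labels of 3 arrays contradicted themselves. The second 4 h TCDD array carried the solvent in its treatment field and TCDD in its title, description and protocol. Both 6 h solvent arrays carried 6 h in title and time field and 4 h in description and protocol. Titles set the groups.

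The deposited table held log2 values per probe set, made with RMA per the submitters' processing notes, with no version given; software, further filters and the genome build were not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of a set. The authors' log2 values ran from 2.2 to 14.1 with 1 decimal, and the median was 5.1 on every array, so a shift of all genes together would not be visible. Differences are compressed near background, so folds from levels near the filter value, such as those of Cyp1a1 in solvent and Rgs4 with TCDD, are uncertain in size. Rounding to 1 decimal gave a few tied values and left 2 tested probe sets with no residual spread. No scanner files were used here, and no depth applies to arrays: their number, 2 per group, limited the precision. All 12 columns of values were used and 0 were left out.

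Of 22690 probe sets, 64 controls were set aside. The platform annotation gave 20380 of the other 22626 probe sets 1 gene symbol, 691 several and 1555 none; genes were named only for the first kind. Of these, 20351 were matched through their gene identifier to a RefSeq table of assembly GRCm38.p6, which changed 0 symbols; no coordinates were taken from it. Probe sets with a mean over the 12 arrays at or above the 30th percentile (log2 3.98) were tested, which left 15844, of which 14566 had 1 symbol, for 9433 genes. Of marker genes on the array, 8 of 16 for cortical and 5 of 12 for medullary thymic epithelium lay above this filter, and 16 of 16 for fibroblasts and mesenchyme; Epcam, Krt18 and Prss16 of the cortical list lay below it. Among all probe sets, the median percentile of the level was 33.6 for cortical, 27 for medullary and 86.8 for fibroblast and mesenchyme markers. The identity of the line was taken from the labels and was not tested, since levels of different probe sets compare only roughly.

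Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups over all 12 arrays (6 residual degrees of freedom) and empirical Bayes variances (prior degrees of freedom 3.81, prior SD 0.218 in log2). Tested were TCDD against solvent at each time, the average of these 3 effects with equal weight, the change of the effect over time (a moderated F-test), and solvent at 4 h and at 6 h against solvent at 2 h. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 counted as passed. Errors of log2 changes are standard errors from this fit, and folds are 2 to the power of the log2 change. On simulated data with 200 changed probe sets among 15844, the share recovered at a log2 change of 1 was 52% at 2 h, 48% at 4 h, 60% at 6 h and 96% for the average; at a log2 change of 2 it was 90%, 92%, 98% and 100%. False calls among 15644 unchanged probe sets numbered 16, 7, 6 and 10. The simulation held no array sets and drew independent noise, with changes of up to 4 in log2. Many large changes ease the Benjamini-Hochberg cutoff, so the shares recovered can be too high for the real data. A gene that did not pass is therefore not shown to be unchanged.

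The 12 arrays were also clustered by complete linkage, and the tree was cut into 4 clusters. The largest cluster, of 7 arrays, made 1 set. The 5 arrays of all other clusters were put together as the other set, so they need not be alike. Both sets cut across treatment and time. The fit was repeated with the array set as a block (5 residual degrees of freedom). The sets were defined from these same values, so p-values of the blocked fit are not independent of the data and can be too small, and those for differences between the sets more so. The set block was added after the data were examined. Without the block, a difference between the sets stays in the spread of each group that holds arrays of both. The p-values of that fit can therefore be too large. Replicate numbers in the titles were checked for pairing through the differences between first and second arrays over the tested probe sets. Within a time these differences correlated between solvent and TCDD at 0.37 (2 h), 0.16 (4 h) and 0.71 (6 h), all over 0.1. The replicate number within each time was therefore used as a block in an alternative fit, which had fewer residual degrees of freedom. Nothing in the labels says what the numbers share, and at 2 and 6 h they coincide with the array sets. Between 2 h and 6 h groups the 4 correlations were over 0.1 too (0.24 to 0.37), and between a 4 h group and a group of another time none was (-0.55 to 0.06).

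Gene lists, 23 with 480 genes, were tested with limma's camera, which asks whether a list's genes moved more than the other genes, at a preset correlation between genes of 0.01. It was repeated with a correlation estimated from the arrays and with fry, and p-values were adjusted over the 23 lists of a comparison. A gene stood in a list by its probe set with the highest mean over the 12 arrays. A list needed 5 genes past the filter to be tested. Member counts were made over all probe sets and adjusted over the list alone. The lists, groups, tests and the rule for naming genes were fixed before the data were examined. Per time, the rule took the 15 genes with the largest increase and the 15 with the largest decrease among those past the test. Their TCDD arrays both had to lie on the same side of both solvent arrays. It took 10 each way for the other comparisons, and always the AhR targets with Ahr, Arnt and Ahrr. Any other list member could be named where its list was described, past the test or not. Which of these members to name was not fixed beforehand. Genes taken from the fit with the set block are said to have been chosen after their values were seen.

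Alternatives planned from the start were a replicate block, fits of only the arrays compared, no filter or the 50th percentile (log2 5.10), a pseudocount of 16 on the linear scale, quantile normalization or median centring, variances without moderation or with an intensity trend and robust estimation, a 1.5-fold minimum, leaving out each array, pooled solvent arrays, and other list tests. Added later were the set block, limma array weights, the poly-A spike level as a covariate, averages without the 4 h or without the 6 h time, and list tests with the replicate block within each time or without the first 4 h TCDD array.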

Results

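RNA levels were measured on 12 Affymetrix mouse arrays in ET cells, a line that the labels describe as fetal cortical thymic epithelium, after 2, 4 and 6 h with 5 nM TCDD or with the solvent 1,4-dioxane. Each of the 6 groups of treatment and time held 2 arrays. TCDD is a ligand of the aryl hydrocarbon receptor (AhR), a transcription factor that pairs with Arnt and switches on enzymes of xenobiotic metabolism. The series asked which genes respond to AhR activation in these cells. Values were deposited log2 levels for 15844 tested probe sets, and the number of arrays limited the precision. The arrays were parted into 2 sets that cut across treatment and time, the largest of 4 clusters and all other arrays. The larger set held 7 arrays (3 TCDD and 4 solvent), and the smaller set held 5 (3 TCDD and 2 solvent), namely the second arrays of both treatments at 2 h and at 6 h and the first TCDD array at 4 h. Both 4 h solvent arrays lay in the larger set, so the smaller set gave no value of its own at 4 h. Results are therefore given with the array set as a block and within each set too.

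After 2 h with TCDD, Cyp1a1 and Cpox were higher than in solvent. Cyp1a1, the cytochrome P450 enzyme best known as an AhR target, rose 48.5-fold (probe set 1422217_a_at, log2 change 5.60 ± 0.45 SE, n = 2 against 2), from a log2 level of 4.15 ± 0.21 (SD) in solvent to 9.75 ± 0.64. Cpox, coproporphyrinogen oxidase of haem synthesis, rose 5.46-fold (1422493_at, 2.45 ± 0.24 SE), and its other probe set passed as well. The limma adjusted p was 0.0038 for Cyp1a1 and 0.0132 for Cpox. In all, 3 probe sets of 2 genes passed, all higher. An unadjusted p under 0.05 was reached by 236, where 792 would be expected by chance. With a count so far below chance the fit may be too strict, so few calls do not show a lack of response. Within the array sets the log2 change of Cyp1a1 was 5.30 and 5.90, and that of Cpox 2.40 and 2.50. The set block gave 10 probe sets of 9 genes, 9 higher and 1 lower. With the replicate number as a block within each time, only Cyp1a1 passed (count 1), and Cpox did not (2.45 ± 0.24 SE, adjusted p = 0.109). The count was 0 without either 2 h solvent array or the second 2 h TCDD array (Cyp1a1 adjusted p = 0.131, 0.0876 and 0.0659, with 2.92e-05 to 1 over 27 alternative settings), 1 without the first 2 h TCDD array or either 4 h solvent array (Cpox adjusted p = 0.299, 0.0601 and 0.0601), 9 without either 4 h TCDD array, and 12 against the solvent arrays of all times. No probe set passed at 2, 4 or 6 h when limma was run on only the 4 arrays of the time, or when variances were not moderated.

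The fit with the set block added 7 genes at 2 h, chosen after their values were seen. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 6.5-fold higher (log2 2.70 ± 0.21 SE with the block, limma adjusted p = 0.00184; SE 0.61 and adjusted p = 0.834 without it). This was 1 of its 2 probe sets, while the other gave 1.25 ± 0.32 with the block and did not pass (adjusted p = 0.664). Cdkn1b, which encodes the related inhibitor p27, was higher by 1.35 ± 0.18 (adjusted p = 0.0424), and Socs3, a feedback inhibitor of cytokine signalling, by 1.90 ± 0.25 (adjusted p = 0.0424). The other probe sets of Socs3 gave 1.95 ± 0.28 and 1.35 ± 0.25 (adjusted p = 0.061 and 0.198), the other of Fosl1 1.25 ± 0.19 (0.0669), of Cyp1b1 1.60 ± 0.31 (0.225) and of Rgs4 -0.65 ± 0.21 (1), none past the test. Fosl1, a subunit of the transcription factor AP-1, was higher by 1.30 ± 0.16 (adjusted p = 0.0312), and the xenobiotic enzymes Cyp1b1 and Aldh3a1 by 1.95 ± 0.21 (adjusted p = 0.0152) and 1.60 ± 0.21 (adjusted p = 0.0424). Rgs4, a regulator that shortens G protein signals, fell by 1.45 ± 0.17 (adjusted p = 0.0285). None of the 7 passed at 2 h without the block, where Socs3 and Rgs4 came closest (adjusted p = 0.0602 for both).

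**Figure D1:**
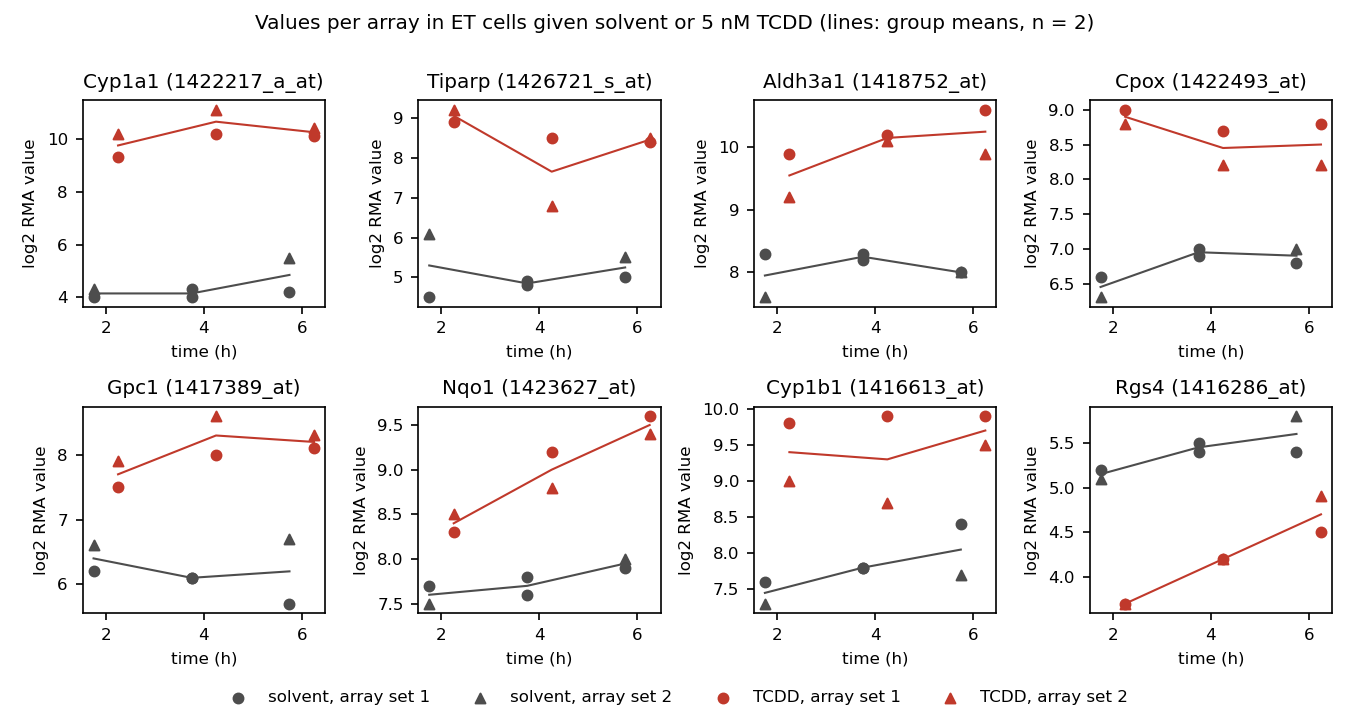
Log2 level (deposited RMA values, y axis) on each of the 12 arrays against time in h (x axis), 1 panel per gene with its probe set; solvent is grey and TCDD red, circles mark arrays of the larger set (set 1) and triangles those of the smaller set (set 2), and lines join the group means (n = 2). Cyp1a1 lay between 4.0 and 5.5 on the 6 solvent arrays and between 9.3 and 11.1 on the 6 TCDD arrays, Nqo1 between 7.5 and 8.0 against 8.3 and 9.6, and Rgs4 between 5.1 and 5.8 against 3.7 and 4.9.

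After 4 h, Cyp1a1 was 90.5-fold higher with TCDD (log2 6.50 ± 0.45 SE, n = 2 against 2; limma adjusted p = 0.000943), with levels of 4.15 ± 0.21 (SD) in solvent and 10.65 ± 0.64 with TCDD. Cpox rose 5.66-fold by 1 probe set (1422492_at, 2.50 ± 0.27, adjusted p = 0.033), while the other stood at 1.5 ± 0.24 (1422493_at, adjusted p = 0.222). These 2 probe sets were the only ones past the test, and 344 had an unadjusted p under 0.05. The replicate block within each time left only Cyp1a1 (count 1), with Cpox at 2.50 ± 0.24 (1422492_at, adjusted p = 0.143). With the set block Cyp1a1 was 70.0-fold higher (6.13 ± 0.26, adjusted p = 1.97e-05) and Cpox 6.45-fold (1422492_at, adjusted p = 0.00173); 7 probe sets of 6 genes passed, all higher. The 4 genes added were chosen after their values were seen: Aldh3a1 (2.12, adjusted p = 0.0151), Gpc1 (1.94, adjusted p = 0.0151), Creb3l1 (1.94, adjusted p = 0.0444) and Cyp1b1 (1.84, adjusted p = 0.037; its other probe set 1.45, adjusted p = 0.689). The treatment field of the second TCDD array named the solvent; without that array 59 probe sets passed, 6 higher and 53 lower, with the remaining TCDD array alone in the smaller set. Without an array of the 2 h solvent, the 4 h solvent or 6 h TCDD only Cyp1a1 passed (count 1; Cpox adjusted p = 0.0749 to 0.644), without a 6 h solvent array the count was 4, and against the solvent arrays of all times it was 9.

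After 6 h, Cyp1a1 was 42.2-fold higher with TCDD (log2 5.40 ± 0.45 SE, n = 2 against 2; limma adjusted p = 0.00532), at 10.25 ± 0.21 (SD) against 4.85 ± 0.92. It was the 1 probe set that passed, and 340 had an unadjusted p under 0.05. Within the array sets its log2 change was 5.90 and 4.90. The replicate block within each time left the count at 1. The set block gave 8 probe sets of 6 genes, all higher. Of these, 5 genes were chosen after their values were seen: Aldh3a1 (2.25, adjusted p = 0.009), Gpc1 (2.00, adjusted p = 0.009), Cyp1b1 (1.65, adjusted p = 0.0384; its other probe set 1.40, adjusted p = 0.602), Cpox (1.60, adjusted p = 0.0309) and Nqo1 (1.55 ± 0.18, adjusted p = 0.023). The description of both 6 h solvent arrays gave 4 h; against the 4 h and 6 h solvent arrays together 11 probe sets passed, and against those of all times 15. The count was 0 without either 6 h TCDD array (Cyp1a1 adjusted p = 0.0975 and 0.152, with 4.08e-05 to 0.986 over 28 alternative settings) and 7 without either 4 h TCDD array.

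Averaged over the 3 times, TCDD raised 10 named genes and lowered 1. Cyp1a1 rose 57.0-fold (log2 5.83 ± 0.26 SE, n = 6 against 6; limma adjusted p = 1.4e-05). Tiparp, an ADP-ribosyltransferase that is itself induced by AhR and restrains it, rose 9.51-fold (3.25 ± 0.32, adjusted p = 0.00313), and all 3 of its probe sets passed. The detoxifying enzymes Aldh3a1, Cyp1b1 and Nqo1 rose 3.78-fold (1.92 ± 0.18), 3.25-fold (1.70 ± 0.23) and 2.32-fold (1.22 ± 0.11), with adjusted p = 0.00227, 0.0321 and 0.00227. A second probe set of Cyp1b1 stood at 1.40 ± 0.23 (adjusted p = 0.0973). Cpox rose 3.61-fold (1.85 ± 0.14, adjusted p = 0.000746).

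Outside the known AhR enzymes, Gpc1, a heparan sulfate proteoglycan of the cell surface, rose 3.56-fold on average (log2 1.83 ± 0.19 SE, n = 6 against 6; limma adjusted p = 0.00367). Creb3l1, a membrane-bound transcription factor of the secretory pathway, rose 2.61-fold (1.38 ± 0.14, adjusted p = 0.00313). Antxr2, a cell surface receptor for matrix proteins and anthrax toxin, rose 2.30-fold (1.20 ± 0.14, adjusted p = 0.00853), and Ptx3, a secreted pentraxin of innate immunity, 2.22-fold (1.15 ± 0.16, adjusted p = 0.0351). Rgs4 was lower (1416286_at, -1.20 ± 0.11, adjusted p = 0.00227), while a second probe set of Rgs4 gave -0.35 ± 0.12 (adjusted p = 1). Mean log2 levels of Rgs4 at 2, 4 and 6 h were 5.15, 5.45 and 5.60 in solvent and 3.70, 4.20 and 4.70 with TCDD. The first of the TCDD levels lay below the filter value of 3.98, so the size of the decrease is uncertain. With the filter at the 50th percentile Rgs4 was not tested (14 probe sets past the test, 14 higher and 0 lower). For each of the 10 higher genes, 6 of 6 TCDD arrays lay above the solvent mean of their time, and for Rgs4 0 of 6 did. The genes were called on these same arrays, so this is no independent evidence. The 1 probe set past the test without a single gene symbol, 1417225_at, was higher by 1.08 ± 0.13 (adjusted p = 0.0121).

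In total 15 probe sets passed on the average, 14 higher and 1 lower, of 11 genes; 533 had an unadjusted p under 0.05, where 792 would be expected by chance. The probe sets past the test at 2, 4 and 6 h (3, 2 and 1) were all among them. Within the larger set of arrays the log2 change of Nqo1 was 0.60, 1.5 and 1.70 at 2, 4 and 6 h, and within the smaller set 1.00 and 1.40 at 2 and 6 h; for Rgs4 these values were -1.5, -1.25 and -0.90, and -1.40 and -0.90. The count was 24 without either 4 h TCDD array, 9 without the 4 h time and 6 without variance moderation. Antxr2 did not pass without the first 2 h solvent array (adjusted p = 0.0576) or either 4 h solvent array (0.0578 and 0.0584), with 0.00215 to 0.147 over 28 alternative settings. Without the 4 h time Gpc1, Creb3l1 and Antxr2 did not pass (limma adjusted p = 0.0534, 0.079 and 0.0693). Neither did Cyp1b1 (0.115) and Ptx3 (0.304). Over the 28 settings adjusted p ran from 0.00016 to 0.147 for Gpc1 and from 0.00218 to 0.139 for Creb3l1. With the replicate number as 1 block over all times, Cyp1b1 and Ptx3 did not pass (limma adjusted p = 0.0701 and 0.0734). Cyp1b1 failed in 14 of the 28 settings, among them every single array left out except the second 2 h TCDD array and both 4 h TCDD arrays (adjusted p = 0.0507 to 0.176 without the others). Ptx3 failed in 15, among them every single array left out except the first 2 h and second 4 h TCDD arrays (adjusted p = 0.0553 to 0.203), while Cyp1a1, Cpox and Nqo1 passed in all 28.

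**Figure D2:**
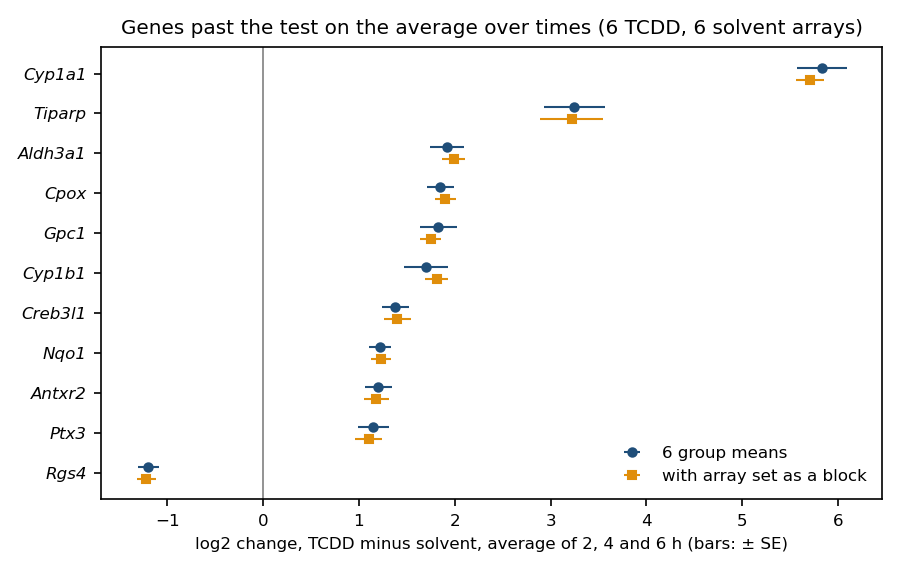
Log2 change with TCDD averaged over 2, 4 and 6 h (x axis) for the 11 genes past the test (y axis), without (circles) and with (squares) the array set as a block; points are estimates from 12 arrays and bars their SE. Values without the block ran from 5.83 ± 0.26 for Cyp1a1 to -1.20 ± 0.11 for Rgs4.

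With the replicate number as a block within each time, 16 probe sets passed on the average, against 15 without a block. With the set block, 46 probe sets passed (43 higher and 3 lower, 34 genes higher and 3 lower), and 817 had an unadjusted p under 0.05. All 15 probe sets above were among them, and Cyp1a1 was then 52.3-fold higher (log2 5.71 ± 0.15 SE, limma adjusted p = 1.79e-07). The genes added were chosen after their values were seen. They held the kinase inhibitors Cdkn1a (1.38 ± 0.12, adjusted p = 0.00194, by 1 probe set; 0.35 ± 0.19, adjusted p = 0.998 by the other) and Cdkn1b (0.77, adjusted p = 0.0188) and the transcription factor subunits Fosl1 (0.89 ± 0.09, adjusted p = 0.00426) and Maff (0.98 ± 0.14, adjusted p = 0.0262). They also held 3 secreted signals: Tslp, an epithelial cytokine that acts on lymphoid and dendritic cells (1.16 ± 0.14, adjusted p = 0.0127), Gdnf, a neurotrophic factor (0.96 ± 0.15, adjusted p = 0.046), and Grem1, an antagonist of bone morphogenetic proteins (0.93, adjusted p = 0.0349). Xdh, xanthine dehydrogenase, was higher by 0.71 ± 0.09 (adjusted p = 0.0127) and Cbr3, a carbonyl reductase, by 0.94 (adjusted p = 0.0262). Lower with Rgs4 were the chemokine Ccl7 (-0.89 ± 0.14, adjusted p = 0.0452) and the zinc finger gene Zfp503 (-0.71 ± 0.11, adjusted p = 0.0361; its other probe set -0.60 ± 0.12, adjusted p = 0.113). Without the block the limma adjusted p was 0.365 for Cdkn1a, 0.126 for Tslp, 0.117 for Gdnf, 0.161 for Grem1 and 0.893 for Ccl7. Mean log2 levels in solvent were 4.00 to 4.15 for Gdnf and 4.25 to 4.55 for Tslp. These lie near the filter value of 3.98, so the sizes of both changes are uncertain. With the block and without the first 4 h TCDD array 74 probe sets passed, 70 higher and 4 lower.

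The list of known AhR targets rose as a group at every time. Of 20 genes fixed, 14 were on the array and 10 were tested; 1 passed over all probe sets at each time (Cyp1a1) and 4 on the average (Cyp1a1, Tiparp, Aldh3a1 and Nqo1). Adjusted over the list alone, 7 rose at 2 h, 6 at 4 h, 7 at 6 h and 7 on the average. The 3 members that the list alone added on the average were Cyp1b1, here by its probe set with the higher mean, Nfe2l2, the transcription factor NRF2 (1.22 ± 0.21 SE, limma adjusted p = 0.000329 adjusted over the list alone, 0.124 over all), and Xdh (0.67 ± 0.12, 0.000329 and 0.13). Cyp2s1 (0.07 ± 0.15), Slc7a5 (0.02 ± 0.10) and Fmo2 (0.02 ± 0.13) did not pass. Ahrr, Cyp1a2, Gsta2 and Selenbp1 lay below the filter on low values, with mean log2 levels of 3.33, 3.69, 3.70 and 3.60. Arnt stood at -0.03 ± 0.10, and the probe sets of Ahr at -0.95 ± 0.48 and -0.00 ± 0.09 (adjusted p = 1). Median log2 changes of the list were 1.15, 1.20, 1.18 and 1.22 at 2, 4 and 6 h and on the average, with camera adjusted p = 4.47e-25, 2.54e-16, 8.81e-23 and 2.26e-29. The list was the only one to pass with an estimated correlation, with adjusted p = 0.000717, 0.00249, 0.000949 and 0.000451 with an estimated correlation, and 0.00309, 0.00446, 0.00365 and 0.00209 when the set block was added. When the replicate block within each time was added instead, the list passed with an estimated correlation on the average alone (adjusted p = 0.0516, 0.102, 0.0604 and 0.0475 with an estimated correlation).

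At 2 h, 3 other lists passed with the preset correlation. The list of p53 targets and kinase inhibitors was higher (17 genes, median log2 change 0.15, camera adjusted p = 0.0026; adjusted p = 0.106 with an estimated correlation). Its members past the test adjusted over the list alone were Cdkn1a (2.70 ± 0.61 SE) and Cdkn1b (1.35 ± 0.32), the latter not a classical p53 target, while the p53 targets Mdm2 (-0.05 ± 0.26) and Bbc3 (0.45 ± 0.15) did not pass. The TGF-beta responsive list was lower (23 genes, median -0.10, camera adjusted p = 0.0026; adjusted p = 0.268 with an estimated correlation), and Smad6 (-1.20 ± 0.30) and Id3 (-0.85 ± 0.21) fell when adjusted over the list alone; both are also known targets of bone morphogenetic proteins. The ER stress list was higher (23 genes, median 0.15, camera adjusted p = 0.0026; adjusted p = 0.586 with an estimated correlation) with 0 members past the test either way; Ddit4 stood at 1.05 ± 0.32 and the chaperone gene Hspa5 at 0.25. Camera's adjusted p was 0.000854 for each of these 3 lists with the set block; adding an estimated correlation gave adjusted p = 0.107 for the p53, 0.38 for the TGF-beta and 0.493 for the ER stress list. Adjusted over the list alone, the NF-kB target Tnfaip2 (0.90 ± 0.21) and Irf1, an interferon-induced transcription factor (1.00 ± 0.23), also rose at 2 h, in lists that did not pass.

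At 4 h the list of NRF2 antioxidant targets was higher (16 genes, 14 of 16 above 0, median log2 change 0.35, camera adjusted p = 4.08e-05; adjusted p = 0.898 with an estimated correlation). No member passed over all probe sets or adjusted over the list alone; Hmox1, haem oxygenase, stood at 1.5 ± 0.89 SE, Gstm1 at 0.90 ± 0.24 and Gclm at 0.80 ± 0.41. This list was also higher in the smaller set of arrays, which held the first 4 h TCDD array and no 4 h solvent array (median 0.42, camera adjusted p = 0.00021; adjusted p = 0.438 with an estimated correlation). Its median at 4 h was 0.17 with the set block (camera adjusted p = 0.000636; adjusted p = 0.625 with an estimated correlation), and without the first 4 h TCDD array camera's adjusted p was 0.272. With the replicate block within each time the immediate early list was higher at 4 h as well (camera adjusted p = 0.00144 against 0.0595 without it; adjusted p = 0.848 with an estimated correlation). Without the first 4 h TCDD array its adjusted p was 0.977. At 6 h the G2/M cell cycle list was higher (22 genes, median 0.15, camera adjusted p = 0.0158; adjusted p = 0.842 with an estimated correlation), with Mki67 at 1.40, Bub1 at 0.75 and Ttk at 0.70 and 0 members past the test either way. The G2/M list was lower in the smaller set of arrays (median -0.33, camera adjusted p = 0.00112; adjusted p = 0.483 with an estimated correlation), and at 6 h each treatment had 1 array in each set. At 4 h the G2/M list did not pass (camera adjusted p = 0.272, direction down). It was higher there without the first 4 h TCDD array (camera adjusted p = 0.00499; adjusted p = 0.777 with an estimated correlation).

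On the average, 3 lists passed besides the AhR targets. The NRF2 targets were higher (median log2 change 0.23, 13 of 16 above 0, camera adjusted p = 0.000112, and 0.625 with an estimated correlation), with 0 members past the test. Nqo1, which passed on the average, was counted among the AhR targets and not in this list. The TGF-beta responsive list was lower (median -0.10, camera adjusted p = 0.0105; adjusted p = 0.383 with an estimated correlation), with Smad6 (-0.70 ± 0.17 SE) and Id3 (-0.57 ± 0.12) past the test adjusted over the list alone; 6 members passed in this way with the set block, among them Id1 (-0.86) and Tgfb2 (-0.45). The p53 target and kinase inhibitor list was higher (median 0.07, camera adjusted p = 0.0167, and 0.212 with an estimated correlation). Its members Cdkn1a (1.57 ± 0.35) and Cdkn1b (0.68 ± 0.18) again passed the test adjusted over the list alone. The list was not tested without them. Without the first 4 h TCDD array the NRF2 and TGF-beta lists no longer passed (adjusted p = 0.0697 for both).

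For the other 19 lists no shift passed on the average: medians ran from -0.10 to 0.07 and camera's smallest adjusted p was 0.0926, for G1/S genes (median log2 change -0.10). NF-kB and inflammatory genes went both ways: of 24, Tnfaip2 rose (0.48 ± 0.12 SE) and Ccl2 (-0.65 ± 0.18), Ccl7 (-0.78 ± 0.24) and Csf1 (-0.48 ± 0.10) fell when adjusted over the list alone, with a median of -0.03. Other probe sets of Csf1 gave -0.15, -0.22 and -0.58. Among 28 immediate early genes, whose median was 0.03, Maff rose in this way (1.10 ± 0.25). Medians were 0.03 for the AhR complex and coregulators, -0.06 for extracellular matrix and adhesion, 0.03 for G2/M, -0.02 for ER stress, -0.03 for hypoxia targets, -0.04 for cholesterol and fatty acid synthesis, -0.02 for interferon and antigen presentation, -0.05 for the circadian clock, 0.07 for heat shock and -0.05 for Notch and Wnt signalling. Marker lists stood at 0.05 for cortical and -0.02 for medullary thymic epithelium, -0.03 for thymocytes, -0.06 for fibroblasts and mesenchyme, -0.03 for endothelium and 0.06 for macrophages and dendritic cells. Thy1 is both in the thymocyte and in the fibroblast list. The G2/M list passed too with the set block (higher, camera adjusted p = 0.00958; adjusted p = 0.784 with an estimated correlation). It also passed without the first 4 h TCDD array (higher, camera adjusted p = 1.83e-05; adjusted p = 0.621 with an estimated correlation). At the single times 19 lists did not pass at 2 h, 21 at 4 h and 21 at 6 h.

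The change of the TCDD effect between 2, 4 and 6 h was tested directly, and 0 probe sets passed limma's F-test, with 105 at an unadjusted p under 0.05; with the set block 0 passed (236 unadjusted), and without variance moderation 0. Per-time log2 changes were 5.60, 6.50 and 5.40 for Cyp1a1, 3.75, 2.80 and 3.20 for Tiparp, 0.80, 1.30 and 1.55 for Nqo1, and 1.60, 1.90 and 2.25 for Aldh3a1. For none of these genes was a difference between the times shown by the test over all probe sets. Chance would give 792 probe sets at an unadjusted p under 0.05, so the test may be too strict, and equal effects are not shown.

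In solvent alone, the list of immediate early genes was lower later than at 2 h by camera with the preset correlation only. Such genes respond within minutes to serum or a medium change, but an effect of either was not tested. At 4 h against 2 h the list's median log2 change was -0.65 with 1 of 28 genes above 0 (camera adjusted p = 8.11e-09; adjusted p = 0.54 with an estimated correlation). Ccn2 stood at -1.70 ± 1.20 SE, Atf3 at -1.45 ± 0.86 and Fosl1 at -1.05 ± 0.66, none past the test. At 6 h against 2 h the median was -0.47 with 2 of 28 above 0 (camera adjusted p = 0.00145; adjusted p = 0.893 with an estimated correlation). Both comparisons share the 2 h solvent arrays, and this list was also higher in the smaller set of arrays, which held 1 of the 2 solvent arrays at 2 h and at 6 h and 0 at 4 h (median 0.65, camera adjusted p = 1.94e-07; adjusted p = 0.483 with an estimated correlation). Its medians were -0.36 (camera adjusted p = 0.00075) and -0.47 (4.39e-05) with the set block, with adjusted p = 0.743 and 0.757 with an estimated correlation. No probe set passed limma's test at 4 h (286 at an unadjusted p under 0.05) or 6 h (447), with the set block (455 and 899) or without variance moderation, where both counts were 0.

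At 4 h in solvent, 4 further lists were lower with the preset correlation: TGF-beta responsive genes (median log2 change -0.20, camera adjusted p = 0.00101), hypoxia targets (-0.23, 0.00116), cholesterol and fatty acid synthesis (-0.20, 0.00335) and heat shock (-0.23, 0.0228), each with adjusted p = 0.54 with an estimated correlation. These 4 camera values were 0.0102, 0.106, 0.0854 and 0.286 with the set block, and the first had adjusted p = 0.658 with an estimated correlation. At 6 h, G1/S genes (median 0.15, adjusted p = 0.0193) and the ER stress list (0.20, 0.0264) were higher, and Notch and Wnt signalling (-0.15, 0.0264) and medullary thymic epithelium markers (-0.20, 0.0264) lower, each with adjusted p = 0.837 with an estimated correlation. The only member past the test adjusted over the list alone was Krt5, a keratin of medullary epithelium (-0.80 ± 0.18 SE, limma adjusted p over all probe sets 0.97); the medullary list had 5 tested genes and camera's adjusted p was 0.0548 with the set block. With the replicate block within each time 2 lists more were lower in solvent: NRF2 targets at 4 h (camera adjusted p = 0.0224 against 0.0908 without it; adjusted p = 0.611 with an estimated correlation) and TGF-beta responsive genes at 6 h (0.033 against 0.0931; adjusted p = 0.769 with an estimated correlation). The labels of the 6 h solvent arrays conflicted as to time.

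The 2 sets of arrays differed in 1480 probe sets of 1130 genes, 592 higher and 888 lower in the smaller set. The metal-binding metallothioneins Mt1 and Mt2 were 8.11-fold and 8.57-fold higher there; Mt1 stood at a mean log2 level of 10.32 (range 9.6 to 10.8, n = 5) against 7.30 (7.1 to 7.4, n = 7). A second probe set of Mt1 differed by 0.72 ± 0.16 SE (adjusted p = 0.0262). Ptgs2, the inducible cyclooxygenase, was 4.59-fold higher, the matricellular gene Ccn2 4.17-fold, Hmox1 2.95-fold and the cytokine Il6 2.79-fold. Ahr was 2.68-fold lower there by 1 probe set, the growth factor receptor Pdgfrb 2.57-fold by 1 probe set and Bmp4 2.39-fold; the other probe sets of Ahr (log2 0.12 ± 0.08 SE, adjusted p = 0.352) and Pdgfrb (-0.30 ± 0.11, adjusted p = 0.115) did not pass. Lists of immediate early genes, NRF2 targets (median log2 difference 0.42), hypoxia targets (camera adjusted p = 0.000947), heat shock (0.0118), cholesterol synthesis (0.0118), ER stress (0.0206) and macrophage markers (0.0206) were higher and G2/M lower there with the preset correlation; none passed with an estimated correlation, and the AhR targets did not differ by camera (adjusted p = 0.807). The sets were defined from these values, so the tests describe the sets and are no independent evidence. The poly-A spike controls, RNAs added before labelling, averaged 9.36 ± 0.29 (SD, n = 7) in the larger set and 8.05 ± 0.63 (n = 5) in the smaller one, a difference past the two-sided exact permutation test (p = 0.00126, 792 splits; adjusted over 4 quality measures 0.00253). The 3' minus 5' signal of actin was 0.76 ± 0.05 against 0.56 ± 0.05 (exact p = 0.00126, adjusted 0.00253) and that of Gapdh 0.10 against 0.06 (exact p = 0.346, adjusted 0.346). Hybridisation controls gave 10.60 against 10.09 (exact p = 0.0619, adjusted 0.0825).

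**Figure D3:**
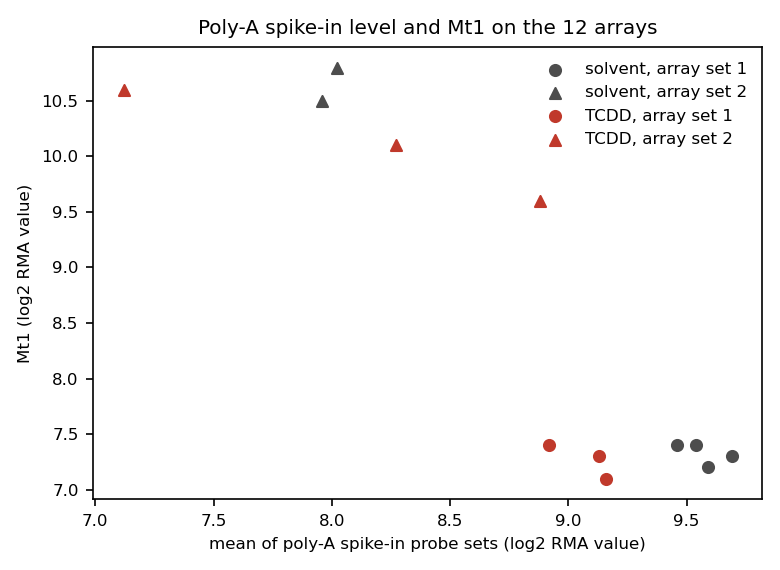
Mean log2 level of the poly-A spike controls (x axis) against the log2 level of Mt1 (y axis) on the 12 arrays; solvent is grey and TCDD red, with circles for the larger set (set 1) and triangles for the smaller (set 2). The 7 arrays of the larger set lay between 8.92 and 9.69 for the spikes and between 7.1 and 7.4 for Mt1, the 5 arrays of the smaller set between 7.12 and 8.88 and between 9.6 and 10.8.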

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

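The tests of macrophages, endothelial cells and thymocytes, of RNA degradation and of the labels of the 4 h TCDD arrays were chosen only after the result was seen, as were the set block and the list tests with the replicate block or without the first 4 h TCDD array, and the sorting of other splits by their makeup.

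For 5 gene list results the TCDD effect differed between times by camera with the preset correlation. The NRF2 list was higher at 4 h than at 2 h (adjusted p = 0.0196, median log2 difference 0.25; adjusted p = 0.97 with an estimated correlation, 0.133 with the set block, 0.635 without the first 4 h TCDD array). The G2/M list was lower at 4 h than at 2 h (adjusted p = 0.0196, median -0.33; 0.97, 0.315 and 0.372 in the same order) and higher at 6 h than at 4 h (adjusted p = 0.00193, median 0.28; 0.805, 0.0643 and 0.895). Without the first 4 h TCDD array both G2/M directions turned: the list then stood higher at 4 h than at 2 h and lower at 6 h than at 4 h, neither past the test. The list of the AhR complex and its coregulators was higher at 6 h than at 2 h (adjusted p = 0.00971, median 0.35; adjusted p = 0.374 with an estimated correlation, 0.00319 with the set block, 0.00178 without the array; 0.255 with the set block and an estimated correlation). The ER stress list was lower at 6 h than at 2 h (adjusted p = 0.00971, median -0.30; 0.878, 0.00221, 0.0104 and 0.752 in that order). Members past the test numbered 0 in each of these lists. With the replicate block within each time all 5 passed (adjusted p = 0.0062, 0.0275, 0.00097, 0.0068 and 0.0068 in the order given; 0.777, 0.91, 0.69, 0.734 and 0.734 with an estimated correlation). For 6 h minus 4 h it added the NRF2 (0.0246), immediate early (9.64e-05) and hypoxia lists (0.0172), all lower and each with adjusted p = 0.69 with an estimated correlation.

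The first pattern was the split of the arrays into sets of 7 and 5, which cut across treatment and time. Macrophages, endothelial cells or thymocytes as the whole source were argued against: over all their markers, dim ones included, the largest median difference between the sets was 0.17 ± 0.10 (SE, log2) for 13 macrophage and dendritic cell markers, against 0.00 ± 0.10 for 10 endothelial and 0.11 ± 0.06 for 13 thymocyte markers, while Mt2 differed by 3.10 ± 0.24 and Lyz2, an abundant macrophage transcript, lay between 4.2 and 5.1 on all 12 arrays. A differing share of cells stays open. In the smaller set 11 of 13 macrophage and 10 of 13 thymocyte markers were higher, by up to 1.05 and 0.49, against 5 of 10 endothelial ones. Most lay below the 50th percentile (10 of 13 macrophage, 9 of 13 thymocyte, 6 of 10 endothelial), and differences near background are compressed. The 6 macrophage markers past the filter were higher there (median 0.30, camera adjusted p = 0.0206, and 0.483 with an estimated correlation). Lower there were 5 of 16 fibroblast and mesenchyme markers (list median -0.35, camera adjusted p = 0.118, and 0.527 with an estimated correlation). RNA amount or labelling yield may have a part, since the poly-A spikes differed between the sets. Arrays of the larger set with lower spikes should then lie further toward the smaller set, which is a negative r. Within the larger set no such relation was shown (Pearson r = 0.23, exact p = 0.587, Spearman rho = 0.21, exact p = 0.662, and r = 0.62 without the 2 farthest of 7 arrays). Spike levels in that set were 9.46 to 9.69 with solvent and 8.92 to 9.16 with TCDD. Spike level and treatment were therefore mixed, and the correlation cannot decide on RNA amount. RNA degradation stayed open too, because actin's 3' minus 5' signal differed between the sets and that of Gapdh did not pass (exact p = 0.346). No biological explanation other than these cell types was tested, because neither treatment nor time parts the arrays in this way. The replicate numbers part them in this way at 2 and 6 h but not at 4 h. What the numbers share is not given in the labels, so a difference tied to them stays open.

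The second pattern was the conflict between labels. That the second 4 h TCDD array was mislabelled as to treatment was argued against: its Cyp1a1 log2 level was 10.2, where the highest of 6 solvent arrays had 5.5 (mean 4.38 ± 0.56 SD). The first 4 h TCDD array, which correlated least with the other arrays (mean r = 0.970), had 11.1. Cyp1a1 was taken as the deciding value after 6 of 7 responding AhR targets on the second array and 5 of 7 on the first were seen to lie above all 6 solvent arrays. Whether the 6 h solvent arrays were mislabelled as to time cannot be told apart, since limma with the set block called 0 probe sets between them and the 4 h solvent arrays (765 at an unadjusted p under 0.05; 0 and 425 without the block), and it also called 0 between 4 h and 2 h, where no label conflicts.

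The third pattern was what other splits of the 12 arrays gave for the average over the times, in 100 drawn splits with the real one included. In 3 of 100 splits as many probe sets passed as the real 15. This share cannot exclude chance, since many other splits kept part of the TCDD effect and the rest left it in the residual. The splits also took no account of the replicate numbers. The highest other split gave 583 and another 290. All 5 arrays of the smaller set lay in 1 group in 3 splits, these and another that gave 3 probe sets; what set the high counts was not tested. With the set block 2 of 100 splits gave as many as the real 46, and the highest other gave 394 (the split with 583), while the split with 290 gave 0. For the number of gene lists chance cannot be excluded: 46 of 100 splits gave as many as the real 4, and the highest other gave 11. The AhR list by itself passed in the real split, in 35 of 57 others that divided the TCDD arrays unequally, and in 0 of 42 that divided them equally. Unequal splits keep part of the TCDD effect and equal ones largely cancel it. These counts for the AhR list were therefore largely fixed in advance and are no evidence on it.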

How the results depend on the processing

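The set block, array weights, spike covariate, averages without a time, the list tests without the first 4 h TCDD array or with the replicate block, and the average with the set block and without that array were chosen only after the result was seen. The G2/M list reversed without the first 4 h TCDD array, from lower to higher for 4 h minus 2 h (adjusted p = 0.372; 0.799 with an estimated correlation) and from higher to lower for 6 h minus 4 h (0.895; 0.963 with an estimated correlation); the cause was not tested beyond the array left out. No other result past the test reversed in the settings run. For the 11 genes called on the average, 267 of 307 values in other settings stayed past the test and 40 did not; for the calls at 2, 4 and 6 h these were 40 and 14, 40 and 14, and 24 and 4.

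Counts at 2 h (3 as reported) were 1 with a replicate block per time, 0 with only the arrays compared, 0 without variance moderation, 12 (11 higher, 1 lower) against the solvent arrays of all times, 10 with the set block and 9 with array weights, and 0 to 9 when each array was left out. At 4 h (2 as reported) they were 1 with the replicate block, 1 with it per time, 0 with only the arrays compared, 1 with a pseudocount of 16, 0 without moderation, 9 (8 higher, 1 lower) against all solvent arrays, 7 with the set block, 1 with array weights, and 1 to 59 with an array left out. At 6 h (1 as reported) they were 0 with only the arrays compared, 2 with the pseudocount of 16, 0 without moderation, 15 against all solvent arrays, 11 against those of 4 and 6 h, 8 with the set block, 3 with array weights, 2 with the spike covariate, and 0 to 7 with an array left out. For the average (15 as reported) they were 6 without moderation, 46 with the set block, 9 without the 4 h time, 74 with the set block and without the first 4 h TCDD array, and 10 to 24 with an array left out; other settings gave 12 to 18. The fits without moderation, on fewer arrays or with a block have fewer degrees of freedom. Otherwise the cause was not tested. The change over time and both solvent comparisons gave 0 in every setting.

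Gene lists past the test with an estimated correlation, with fry, and with the set block and an estimated correlation numbered 1 each at 2, 4 and 6 h and on the average (4, 2, 2 and 4 as reported), as they did without the first 4 h TCDD array and with an estimated correlation,, and 0 each for the solvent comparisons at 4 and 6 h (5 and 5) and for the effect differences 4 h minus 2 h, 6 h minus 4 h and 6 h minus 2 h (2, 1 and 2). With the set block and the preset correlation there were 5 at 6 h, 3 for solvent at 4 h and 1 for 4 h minus 2 h; for 6 h minus 4 h there were 4 with the mean of each gene's probe sets and with the replicate block per time, and 0 without the first 4 h TCDD array. With the replicate block per time and an estimated correlation there were 0 at 2, 4 and 6 h, 1 on the average and 0 for the other 5 comparisons. The cause was not tested.

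Over all 15 pairs of groups the correlation of the differences between first and second arrays ran from -0.55 to 0.71, with 7 over 0.1: the 3 within a time and the 4 between 2 h and 6 h groups, where the numbers coincide with the array sets. The replicate block per time ended the Cpox calls at 2 and 4 h and the list calls with an estimated correlation named beside those results. Cpox kept its log2 change with an SE no larger (2.45 ± 0.24 in both fits at 2 h, 2.50 ± 0.24 against 2.50 ± 0.27 at 4 h). Its calls were thus not lost to a smaller effect or a larger spread, and this block leaves fewer residual degrees of freedom. For the list calls the cause was not tested. With the preset correlation the block added 6 list calls and ended 0, and it changed no other call of a gene named in the fit without a block. Median centring moved nothing, since all medians were equal, and quantile normalization put the median change of all probe sets at -0.01. Fits of only the arrays compared give nothing distinct for the average and the change over time. Each lone array left in a group was assumed to vary like the other groups. What signal over background allowed limits genes below the filter, such as Ahrr.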

Other observations

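The bounds of the time course test were set before its own result was seen, but its genes come from the fit with the set block, and that fit was chosen only after the result was seen, as was the test of the genes' other probe sets.

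A hypothesis was that the TCDD effect changes between 2 and 6 h for some called genes, so that a response at 2 h that is smaller later may stand beside the lasting one of Cyp1a1. Of the 37 genes called on the average with the set block, 2 passed the F-test of the change of effect adjusted over these genes alone, and both had a smaller effect at 6 h than at 2 h. For Cdkn1a the log2 change was 2.70, 1.03 and 0.40 at 2, 4 and 6 h (6 h minus 2 h -2.30 ± 0.30 SE, limma adjusted p = 0.00276), and for Socs3 it was 1.90, 0.64 and 0.25 (-1.65 ± 0.35, adjusted p = 0.0472). Maff (adjusted p = 0.0532), Cdkn1b and Fosl1 (adjusted p = 0.0615 for both) came next and did not pass. The test rests on 1 probe set per gene. With another probe set of the gene in its place, Cdkn1a gave 1.25, -0.04 and -0.15 (adjusted p = 0.119) and Socs3 1.95, 0.60 and 0.25 (0.0575) or 1.35, 0.51 and 0.30 (0.146), each smaller at 6 h but none past the test, while Fosl1 gave 1.25, 1.13 and 0.15 and passed (0.0399). Without the block 0 of the 37 genes passed, with limma adjusted p = 0.374 for Cdkn1a and 0.0831 for Socs3, and over all probe sets 0 passed in either fit. The genes were picked on the same arrays and with sets drawn from the same values, so this stays a hypothesis.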
